A study of Rattus norvegicus with 12 samples.

How the data were processed

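The 12 arrays are Affymetrix rat expression arrays hybridised with biotin-labelled total RNA, and each held a pool of the RNA of 3 rats, per the labels. The authors deposited 1 intensity per probe set and array on a linear scale, made with Affymetrix Expression Console and the PLIER algorithm per the submitters' processing notes. Versions, background correction and scaling between arrays are not given in the sources used here. The deposited values were all above 0 and their distributions differed between arrays, so the probe set values share no common distribution. Whether a normalization was applied to the probes beforehand cannot be seen from them. Intensities of this kind have no unit in molecules, and at low intensity background makes differences smaller than they are.

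Groups came from the labels: streptozotocin or citrate buffer, and the sham operation or the days between ligation and sacrifice. The non-diabetic day 56 array carries an age of 22 weeks in the labels where the diabetic one has 26, and its protocol gives 56 days; it was kept at day 56, and results without it or its pair are given. The tissue label of both sham arrays speaks of an infarct while their protocol describes a sham operation; the protocol was followed. How long after the sham operation those rats were killed is not given in the sources used here. The RNA of a pool is 1 sample, so each condition and time point had 1 sample.

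The table held 31099 probe sets. After 57 control probe sets were taken out, 31042 remained, of which 20826 had 1 gene symbol in the platform annotation, 436 had several and 9780 were not listed. No gene was named from a probe set with several symbols. For 20758 probe sets with 1 symbol the Entrez ID was found in the reference table of rat genes, and 0 symbols changed through it. Values were used as log2 of the intensity plus 16, so fold changes are on that scale and understate the change of dim genes. Probe sets with a mean log2 value above the 40th percentile were kept, which left 18625, or 14310 with 1 symbol for 10623 genes. No further scaling between arrays was applied in the main setting. A gene is represented by its probe set with the highest mean over all 12 arrays.

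Differences were tested with limma 3.58.1 in R 4.3.3. A linear model with the time point as a factor of 6 levels and diabetes was fitted to all 12 arrays, which leaves 5 residual degrees of freedom, with moderated variances that follow a trend on the mean, and p-values were adjusted by Benjamini-Hochberg over the 18625 probe sets within each comparison, at a threshold of 0.05. The comparisons were diabetic minus non-diabetic, the mean of the 5 days minus sham, each day minus sham, and the slope on log2 of the day over the 5 days. The interaction of diabetes with ligation was fitted on 12 arrays and that with log2 of the day on the 10 ligated arrays. Errors are the model's standard errors. The tests, lists of genes, rules for naming genes and first set of alternatives were fixed before the data were examined.

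For lists of genes, limma's camera compared a list's members with all other genes, 1 probe set per gene, with a preset correlation of 0.01 and also with the correlation estimated from the residuals, adjusted over the lists within a comparison. As camera sets a list against all other genes, a shift of all genes on an array cancels in it. Of the lists 34 had 4 or more measured members; brown adipocyte markers had 3 and were not tested. Members past the threshold were counted over all genes and adjusted over the list alone. The tests of lists on single days were chosen after seeing the data.

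Named genes follow a rule. For diabetes and the slope they are the 12 higher and 12 lower genes with the largest change among those past the threshold, for diabetes also with 1 direction at all 6 time points. For the mean of the 5 days fewer than 5 genes passed with all 10 ligated arrays on the same side of sham, so the 10 with the smallest p are given. For each day they are the 5 higher and 5 lower genes with the largest change, within a list up to 4 members with the smallest p, and for single time points the 5 higher and 5 lower. A set of 16 genes of heart failure and metabolism was always looked up, of which 1 is not reported here.

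The pipeline was tested on simulated data with 200 of 18625 probe sets changed. For diabetes a log2 change of 1 was recovered in 96.5% and of 2 in 100%, for the mean of the 5 days in 68% and 99.5%, for a day against sham in 19% and 98.5%, and for the slope in 30% and 99%. No recovered probe set had the wrong sign. Unchanged probe sets called at log2 changes of 1 and 2 numbered 14 and 15 for diabetes, 13 and 14 for the mean of the 5 days, 8 and 9 for a day against sham and 5 and 12 for the slope. For a day at a log2 change of 1 these were 8 beside 38 recovered. In the same kind of data camera recovered 1 of 1 shifted list with 0 others called. A simulated list cannot show whether the preset correlation holds for the measured lists. Their estimated correlations ran from -0.024 for lipogenesis and sterol synthesis to 0.77 for neutrophil markers. The estimate was 0.59 for fatty acid oxidation and 0.75 for matrix genes. The simulated noise was normal and independent between probe sets, and no time effect was added beyond the change tested. The rates of recovery therefore need not hold for the measured arrays, and a day without calls does not exclude large changes.

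Alternatives were offsets of 1 and 64, quantile normalization, array medians set equal, no filter, the upper 40% of probe sets, variances without a trend or with robust shrinkage, the mean of a gene's probe sets, array quality weights, models without time terms, an F test over the 5 days, the rank of the days, and each array or time point pair left out. Restrictions to arrays with a low or high 3' to 5' difference of beta-actin, and without the day 14 and day 28 pairs, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.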

Results

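Gene expression was measured in myocardium of male Sprague-Dawley rats, in the free wall of the left ventricle away from an infarct made by tying off the left anterior descending coronary artery. Rats were made diabetic with streptozotocin at 65 mg/kg, a toxin that destroys the insulin-producing beta cells of the pancreas, or were given citrate buffer alone, and were operated on 10 weeks later. Tissue was taken after a sham operation and at 1, 7, 14, 28 and 56 days after ligation. Each of the 12 arrays held RNA pooled from 3 rats, with 1 diabetic and 1 non-diabetic array at each of 6 time points, so no condition had a second array of its own. The residual spread behind the p-values is therefore how the diabetic minus non-diabetic difference varied over the time points, not a spread between rats. It holds noise between pooled arrays and any change of that difference with time. The tests of days against sham and of the slope use the same spread. The number of arrays limits the precision. The median probe set intensity of an array lay between 28.8 and 34.7.

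The 4 arrays of day 1 and day 7 stood apart from the 8 others in a measure of RNA quality. The log2 difference between the 3' and the 5' probe set of beta-actin, which grows when the 5' part of a transcript is under-represented, was 0.98 to 1.00 on those 4 arrays and 0.37 to 0.59 on the 8 others. The 5' probe set of hexokinase read 0.0587 to 3.19 against 14.2 to 82.9. The 3' to 5' difference of GAPDH did not set these arrays apart, at 0.317 to 0.360 against 0.114 to 0.479. The first principal component, with 40.1% of the variance, took values of 44.3 to 52.8 on the day 1 and day 7 arrays and -59.6 to -1.25 on the others. Every difference between these days and sham or later days below runs along that split. No batch or scan date was available, so separate processing of these 4 arrays cannot be told apart from the days.

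**Figure D1:**
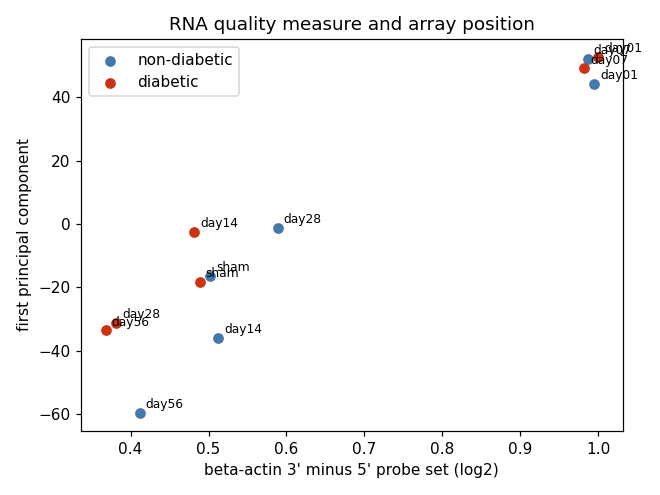
Each point is 1 array, with the log2 difference between the 3' and 5' probe sets of beta-actin on the horizontal axis and the score on the first principal component on the vertical axis, red for diabetic and blue for non-diabetic. The 4 arrays of day 1 and day 7 lie at 0.98 to 1.00 and 44.3 to 52.8, apart from the 8 other arrays.

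Across the 6 pairs of arrays, diabetic myocardium differed from non-diabetic myocardium in genes that handle fatty acids. Acot1, a thioesterase that splits long-chain acyl-CoA, was higher by 2.45 ± 0.15 on the log2 scale (SE, n = 6 pairs), with an adjusted p of 4.9e-05. Pdk4, the kinase that shuts off pyruvate dehydrogenase, was higher by 2.46 ± 0.36, and Angptl4, a secreted inhibitor of lipoprotein lipase, by 2.73 ± 0.49. Card9, an adaptor of innate immune receptors, fell by 3.55 ± 0.24, with an adjusted p of 5.3e-05. Slc2a4, the insulin-responsive glucose transporter GLUT4, fell by 1.25 ± 0.23, with an adjusted p of 0.046.

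Pik3c2g, a class II phosphoinositide 3-kinase, was higher by 2.93 ± 0.19, with an adjusted p of 5.2e-05. Gpihbp1, which carries lipoprotein lipase to the capillary surface, was higher by 1.92, and Decr1, a mitochondrial enzyme of unsaturated fatty acid oxidation, by 1.43. Nudt7, a peroxisomal hydrolase of coenzyme A, was higher by 1.37, and Rbp7, a retinol-binding protein, by 1.72. Cyp1a1, a monooxygenase of xenobiotics, was higher by 2.13, Cbr1, a carbonyl reductase, was 2.83-fold higher, and on the log2 scale Bex1 was higher by 2.02 and Tceal5 by 1.94. Among lower genes, Bdh1, the mitochondrial enzyme that converts the ketone bodies acetoacetate and 3-hydroxybutyrate into each other, had a difference of -1.75 and Cox7a1, a muscle subunit of cytochrome c oxidase, of -1.43. Scn4b, an accessory subunit of the sodium channel, had -1.63, Aplnr, the apelin receptor, -1.47, Scx, a transcription factor of tendon and matrix-forming cells, -1.48, and Sctr, the secretin receptor, -1.90. The other lower genes were Doc2g at -1.56, Dcxr at -1.56, Gcat at -1.36, Fndc5 at -1.35 and LOC100909739 at -1.26. All 24 genes differed in one direction at all 6 time points, as the rule for naming them required. The sizes moved with the offset of 16 where 1 condition lay near or under the filter threshold of 5.20 on the log2 scale. Acot1, at a mean of 4.58 in non-diabetic arrays, was higher by 3.94 with an offset of 1 and by 1.30 with one of 64, Cyp1a1, at 4.49, by 3.77 and 1.06, and Tceal5, at 4.65, by 3.04 and 0.99. Pik3c2g, at 5.33, was higher by 3.74 and 1.98, Angptl4, at 5.43, had differences of 4.05, not past the test, and 1.81, and Card9, at 4.72 in diabetic arrays, of -5.00 and -2.26. Of the genes of heart failure and metabolism looked up in any case, Ucp3 had a difference of 1.14 and Myh6 of -0.73 without passing, with adjusted p-values of 0.069 and 0.091. Nppa at 0.66, Nppb at -0.21, Myh7 at 0.26, Acta1 at -0.030, Atp2a2 at -0.0095, Col1a1 at -0.28, Col3a1 at -0.21, Postn at 0.62, Timp1 at -0.22 and Spp1 at 0.49 did not pass either, with adjusted p-values from 0.199 to 0.980.

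In total 70 of 18625 probe sets passed an adjusted p of 0.05, 28 higher and 42 lower in diabetic arrays. This balance depended on the arrays used. Higher and lower probe sets numbered 47 and 27 without the day 1 pair, and 28 and 7 on sham and days 14 to 56 alone. They numbered 40 and 52 without the day 28 pair, and 20 and 22 without the day 7 pair. The count was 42 without the day 7 pair, 20 without the sham pair, 21 without the day 14 pair and 6 without the day 56 pair. In that last pair the labels give an age of 26 weeks for the diabetic and 22 for the non-diabetic array. Labelled age and diabetes cannot be told apart there. Of the 24 genes, Acot1, Card9, Pik3c2g, Sctr and Tceal5 passed whichever pair was left out, while Doc2g passed in 7 of 20 alternative settings and Angptl4 in 9. Slc2a4, which was looked up in any case, passed in 10 of 20. The 4 arrays of day 1 and day 7 alone gave 2 probe sets, the 8 others 35, and the arrays without day 14 and day 28 gave 38. On the 4 arrays of day 1 and day 7 the difference was 0.86 for Pdk4, 0.88 for Rbp7, 0.75 for Nudt7, -0.97 for Bdh1 and -0.66 for Scx, none of them past the test there, against 3.26, 2.13, 1.68, -2.14 and -1.90 on the 8 others.

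**Figure D2:**
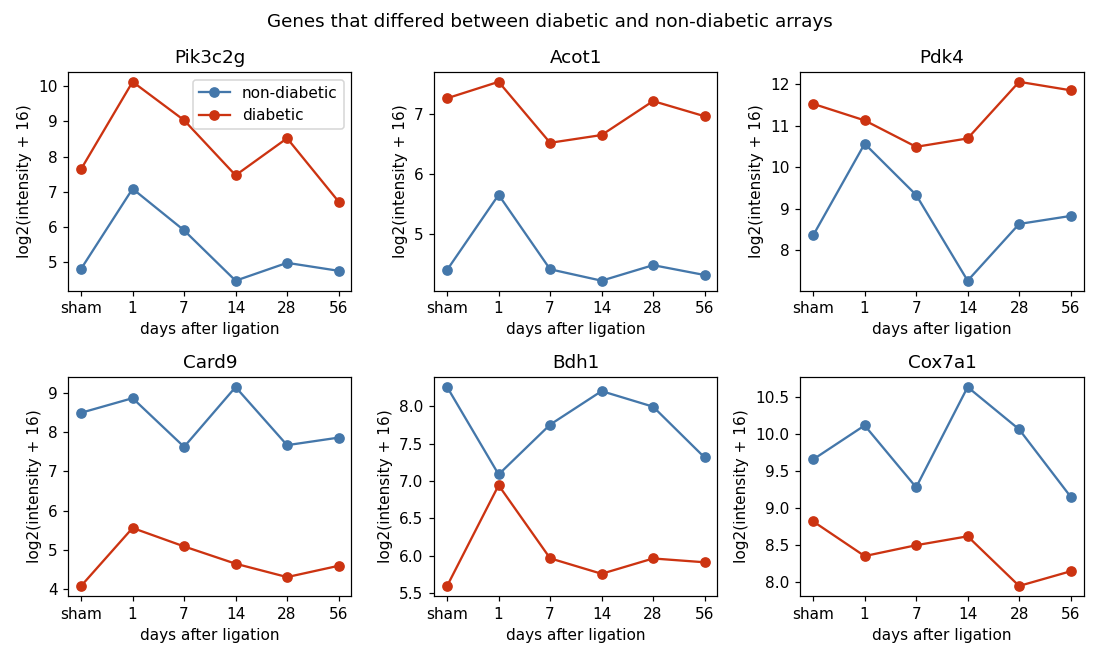
Level of 6 genes on each of the 12 arrays, as log2 of the intensity plus 16, over the sham operation and the days after ligation, with diabetic arrays in red and non-diabetic arrays in blue; each point is 1 array of 3 pooled rats, without an error bar. Pik3c2g, Acot1 and Pdk4 lie higher and Card9, Bdh1 and Cox7a1 lower in the diabetic array at all 6 time points, as the rule for naming them required.

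Among gene lists fixed beforehand, genes of fatty acid oxidation lay higher in diabetic arrays, with 28 of 32 measured members above 0 and a median of 0.41. As a mean over members, the difference was -0.070 on day 1 and 0.42 to 1.07 at the other time points. The set test gave an adjusted p of 2.7e-17 with the preset correlation, and adjusted p = 0.675 with an estimated correlation. Of these 32 members 5 passed the test over all genes, and 15 did when adjusted over the list alone, all higher; they included Acot2, a mitochondrial acyl-CoA thioesterase, at 1.25. Atrial markers had a median of 0.64 with an adjusted p of 0.036, and adjusted p = 0.675 with an estimated correlation; 0 of 7 members passed in limma's test over all genes and 2 when adjusted over the list alone, namely Dkk3 at 0.75 and Nppa, atrial natriuretic peptide, at 0.66. That call was lost without the sham pair, with adjusted p = 0.097, without the day 1 pair, with 0.074, and without the day 7 pair, with 0.065; its median was 0.29 without the day 1 pair and 0.34 without the day 56 pair. On the arrays of sham and days 14 to 56 alone it was 0.28, with an adjusted p of 0.185.

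The 4 other lists that passed were lower, those of complement and antigen presentation, lymphocytes, endothelium and proliferation, with adjusted p-values of 8.0e-04, 0.0021, 0.0043 and 7.4e-04 with the preset correlation. The corresponding values were adjusted p = 0.79, 0.675, 0.675 and 0.675 with an estimated correlation. Of their members 1 passed the test over all genes, Cd74, the invariant chain of class II molecules, at -0.83. Complement and antigen presentation genes, with Cd74, had a median of -0.18, with 5 of 22 past when adjusted over the list alone, among them RT1-Ba at -1.11. Lymphocyte markers had a median of -0.36, with 1 of 9 past when adjusted over the list alone, the T cell receptor subunit gene Cd3e at -0.63. Endothelial markers had a median of -0.21, with 4 of 13 past when adjusted over the list alone, among them Tie1 at -0.82 and Pecam1 at -0.46. Proliferation genes had a median of -0.35, with 6 of 12 past when adjusted over the list alone, among them Ube2c at -0.87 and Cdk1 at -0.71. The complement median was -0.27 without the day 1 pair and -0.073 without the day 28 pair, the endothelial list had an adjusted p of 0.058 on sham and days 14 to 56 alone, and the proliferation list one of 0.059 without the day 14 and day 28 pairs.

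The other 28 lists did not pass for diabetes. Among metabolic lists, the median was -0.17 for ketone body metabolism, -0.038 for glucose uptake and glycolysis, -0.078 for mitochondrial oxidative phosphorylation, 0.024 for lipogenesis and sterol synthesis and 0.14 for insulin signalling. Among heart muscle lists it was -0.030 for hypertrophy and fetal genes, -0.041 for adult contractile genes, 0.079 for calcium handling and -0.078 for potassium and sodium channels. Matrix genes had a median of -0.12, with 3 of 43 lower when adjusted over the list alone, Col15a1 at -1.16, Col4a2 at -0.82 and Sparc at -0.50. That list passed as lower without the day 1, the day 14 or the day 56 pair, with medians of -0.20, -0.27 and -0.30, and had a median of 0.16 without the day 28 pair. The median was 0.11 for inflammation and acute phase genes, -0.0050 for the interferon response, -0.17 for macrophage markers, 0.014 for neutrophil markers and -0.21 for erythroid markers. Without the day 14 and day 28 pairs the interferon list passed as higher, with a median of 0.35 and an adjusted p of 0.0052, and on sham and days 14 to 56 alone erythroid markers passed as lower, at -0.51. It was -0.19 for smooth muscle, -0.088 for fibroblast, 0.11 for adipocyte, -0.22 for mesothelial and epicardial, -0.030 for skeletal muscle and -0.13 for Schwann cell and neural markers. Stress and regulatory lists had medians of -0.059 for heat shock and unfolded protein genes, 0.034 for antioxidant genes and metallothioneins, -0.034 for the circadian clock, 0.23 for immediate early genes and -0.018 for glucocorticoid-responsive genes. The last values were -0.031 for the renin-angiotensin and natriuretic list and -0.045 for apoptosis and autophagy. Txnip, an inhibitor of thioredoxin, passed within the antioxidant list at 1.21 with an adjusted p of 0.0089. The median and the test differed in sign for hypertrophy genes, ion channels, the interferon response, skeletal muscle markers and glucocorticoid-responsive genes, and the median and the mean did so for calcium handling.

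The second comparison followed expression after ligation, each day against sham, and its 5 contrasts share the 2 sham arrays. Rats of later days were also older, from 18 weeks at sham to 26 weeks in the label of the diabetic day 56 array. On day 1, 783 probe sets were higher and 609 lower than in sham over both conditions combined. Slpi, a secreted protease inhibitor, rose by 5.24 ± 0.56 (SE, 2 arrays against 2), Ccl20, a chemokine, by 5.18 ± 0.34, Ccn1, a matrix-associated signalling protein, by 4.75 ± 0.33, Reg3b, a secreted lectin, by 4.23 ± 0.50 and Ankrd2, a stretch-responsive muscle gene, by 4.31 ± 0.37. Timp1, an inhibitor of matrix proteases, rose by 3.52 and Nppb, the ventricular natriuretic peptide, by 1.16. Angptl4 was higher by 3.15 and passed in 4 of 11 alternative settings, with adjusted p-values from 0.0327 to 0.213. Gzmb, granzyme B of cytotoxic lymphocytes, had a change of -4.92 ± 1.17, Kcnn1, a calcium-activated potassium channel, of -2.60, and Slc2a4 of -1.77. Sohlh1, Fcrla and LOC102549347 had changes of -2.93, -2.57 and -2.64.

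On day 1 inflammation and acute phase genes had 12 of 27 members higher over all genes and 14 when adjusted over the list alone, among them Lcn2, a siderophore-binding protein, at 3.64, Cxcl1 at 2.69 and Il1b at 1.96. Hypertrophy and fetal genes had 7 of 11 members higher by either adjustment, among them Fhl1 at 1.47 and Myocd, a coactivator of muscle transcription, at 1.19. Neutrophil markers had 2 of 5 higher over all genes and 4 when adjusted over the list alone, among them Csf3r at 1.61 and S100a8 at 2.48. These 3 lists passed at adjusted p-values of 9.3e-07, 2.0e-04 and 0.031, and had adjusted p = 0.699, 0.699 and 0.706 with an estimated correlation. The 7 lists that were lower included interferon response genes with a median of -0.96, lymphocyte markers with -0.66, potassium and sodium channels with -0.57, in which Kcnip2 had -1.81, and smooth muscle markers with -0.45. The other 3 were fibroblast markers with -0.40, complement and antigen presentation genes with -0.30 and mitochondrial oxidative phosphorylation with -0.12, whose mean was 0.12 in the non-diabetic and -0.26 in the diabetic array; these 7 had adjusted p-values from 9.3e-07 to 0.027. They had adjusted p = 0.699 to 0.782 with an estimated correlation.

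On day 7 matrix genes rose, with 21 of 43 members higher over all genes and 33 when adjusted over the list alone, with 42 above 0 and a median of 1.68. The list passed at an adjusted p of 1.1e-14, and had adjusted p = 0.677 with an estimated correlation. Of single genes, Cthrc1, a secreted protein with a collagen-like stretch, rose by 5.75 ± 0.94, Postn, periostin, by 5.57 ± 1.02, Tnc, tenascin C, by 4.12 ± 0.54, Col1a1 by 3.74 ± 0.60 and Col3a1 by 2.01 ± 0.52. Car3, a carbonic anhydrase abundant in fat and slow muscle, rose by 4.48 and C1qtnf3, a secreted relative of complement C1q, by 4.06. LOC102552995 had a change of -3.96, Kcnn1 of -2.88, Fcrla of -2.63, LOC102549347 of -2.54 and Sohlh1 of -2.51. Macrophage markers had a median of 1.05 with all 19 members above 0, and 1 member, Trem2, a lipid receptor of macrophages, passed over all genes at 1.48, with 7 when adjusted over the list alone.

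Proliferation genes had 4 of 12 members higher over all genes on day 7 and 5 when adjusted over the list alone, among them Prc1 at 1.78 and Cdk1 at 1.97, and the interferon response list had a median of 0.76, with Dhx58, an RNA sensor, at 2.04. The mean of the interferon list was 0.16 in the non-diabetic and 1.36 in the diabetic array, against -0.30 and 0.30 in the sham arrays, so that the diabetic array carried most of its value. Endothelial markers had a median of -0.31, with Aqp1 at -0.92, glucocorticoid-responsive genes -0.44, ion channels -0.020 and oxidative phosphorylation -0.077. The macrophage list passed at an adjusted p of 1.8e-04 and the 6 other lists at 0.0032 to 0.035. All 8 lists of this day had adjusted p = 0.631 to 0.677 with an estimated correlation.

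**Figure D3:**
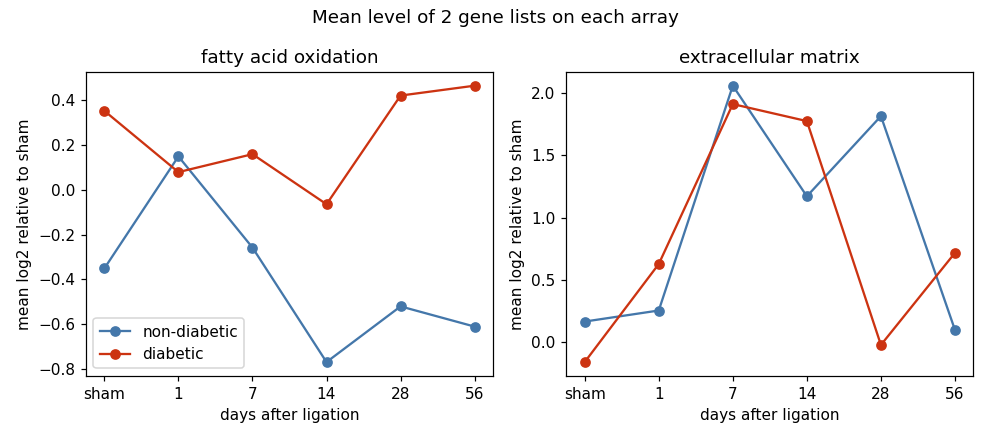
Mean log2 level, relative to the mean of the 2 sham arrays, of the fatty acid oxidation list of 32 genes on the left and the extracellular matrix list of 43 genes on the right, over the sham operation and the days after ligation; each point is 1 array, red for diabetic and blue for non-diabetic. Matrix genes lie highest at day 7 in both conditions and the 2 arrays of day 28 lie far apart.

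On day 1, 1392 probe sets passed, 783 higher and 609 lower, and on day 7, 1424, 870 higher and 554 lower. With quantile normalization the splits were 588 higher and 687 lower, and 435 higher and 630 lower. With array medians set equal they were 621 and 1006 on day 1 and 464 and 1145 on day 7, and the median change of all genes was 0.070 on day 1 and 0.15 on day 7. The 4 arrays of these days are those with a beta-actin difference of 0.98 to 1.00. The day 1 count was 316 without the non-diabetic sham array and 187 without the diabetic one, and the day 7 count 286 and 168. Of 10 named genes each, 9 on day 1 and 5 on day 7 passed whichever sham array was left out: Gzmb lost its call on day 1, and Cthrc1, Postn, Car3, C1qtnf3 and LOC102549347 did on day 7. Nppb, Timp1, Slc2a4 and Angptl4 on day 1 and Col3a1 on day 7 lost theirs without either sham array, with adjusted p-values from 0.066 to 0.272, and Col1a1 on day 7 did without the diabetic one, with 0.054. With offsets of 1 and 64 the calls of LOC102552995, Fcrla, Sohlh1, LOC102549347 and Tnc held, with values on day 7 of -7.16 and -2.25, -4.31 and -1.36, -3.96 and -1.34, -3.66 and -1.43, and 6.46 and 2.48. Day 1 values were -4.10 and -1.35 for Fcrla, -5.88 and -1.47 for Sohlh1 and -3.93 and -1.46 for LOC102549347, and C1qtnf3 had 2.44 on day 7 with an offset of 64. Probe sets of a gene also differed: Myh7 and Myh6 had changes of -0.28 and -0.56 on day 1 and -0.23 and 0.10 on day 7 by their brighter probe sets, none past the test, and of -4.88 and -4.04 on day 1 and -4.65 and -3.64 on day 7, all past it, by their other ones.

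On days 14, 28 and 56 no single gene passed against sham. The limma test called 0 probe sets on each of these days, with 2172, 675 and 3062 at an unadjusted p under 0.05, and 8, 8 and 14 lists passed camera, of which 0, 0 and 0 did with an estimated correlation. The median change of all genes was -0.12 on day 56. Large changes could fail here: Col1a1 at 3.11 and Postn at 2.93 on day 14 each had an adjusted p of 0.402 in limma. Matrix genes had medians of 1.34 on day 14, 0.82 on day 28 and 0.35 on day 56, with adjusted p-values of 4.4e-19, 1.1e-14 and 6.3e-08. The corresponding values were adjusted p = 0.769, 0.618 and 0.621 with an estimated correlation. When adjusted over the list alone, 31 of 43 members passed on day 14, 30 of them higher, and 0 in limma on days 28 and 56, where 7 and 4 had an unadjusted p under 0.05. As a mean over members against the mean of the 2 sham arrays, the list lay at 1.17 in the non-diabetic and 1.78 in the diabetic array on day 14, at 1.82 and -0.025 on day 28 and at 0.095 and 0.72 on day 56, so that 1 array carried the value of day 28 and 1 that of day 56. Interferon response genes had medians of -0.64, -0.73 and -1.43 on these days, with adjusted p-values of 3.0e-04, 1.2e-09 and 4.9e-09. They had adjusted p = 0.769, 0.535 and 0.548 with an estimated correlation.

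Hypertrophy and fetal genes had medians of 0.56, 0.43 and 0.51 on days 14, 28 and 56, with adjusted p-values of 0.0023, 9.1e-05 and 4.2e-06. They had adjusted p = 0.769, 0.488 and 0.278 with an estimated correlation. Fatty acid oxidation genes had a median of -0.45 on day 14, with an adjusted p of 3.0e-07, and adjusted p = 0.769 with an estimated correlation. Their mean was -0.77 in the non-diabetic and -0.065 in the diabetic array, against -0.35 and 0.35 in the sham arrays of these conditions. Proliferation genes had a median of 0.70 on day 14, with 6 of 12 past when adjusted over the list alone and an adjusted p of 1.6e-04, and adjusted p = 0.769 with an estimated correlation. Their mean was 0.97 in the non-diabetic and 0.25 in the diabetic array. Immediate early genes had a median of 0.51 on day 28, with 7 of 18 past when adjusted over the list alone and an adjusted p of 1.4e-10, and adjusted p = 0.488 with an estimated correlation. Macrophage markers had medians of 0.58, 0.30 and -1.02 on days 14, 28 and 56, with adjusted p-values of 0.051, 0.041 and 8.8e-06. They had adjusted p = 0.826, 0.834 and 0.607 with an estimated correlation, and their mean on day 28 was 1.05 in the non-diabetic and -0.40 in the diabetic array.

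The other lists past camera on day 14 were oxidative phosphorylation at -0.13, fibroblast markers at 0.69 and glucocorticoid-responsive genes at -0.33, with adjusted p-values from 4.1e-05 to 0.031, and adjusted p = 0.769 to 0.826 with an estimated correlation. On day 28 they were oxidative phosphorylation at -0.13, inflammation genes at 0.39 and glucocorticoid-responsive genes at 0.40, with adjusted p-values from 2.2e-05 to 0.041, and adjusted p = 0.535 to 0.834 with an estimated correlation. On day 56 they included skeletal muscle markers at 0.53, calcium handling at 0.21, insulin signalling at 0.17, ion channels at 0.14, glycolysis at 0.12 and adult contractile genes, which passed as higher with a median of -0.0047 and a mean of 0.22. These 6 had adjusted p-values from 7.4e-04 to 0.0103, and adjusted p = 0.278 to 0.629 with an estimated correlation.

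Averaged over the 5 days, ligated hearts differed from sham in few single genes. Ranbp1, a regulator of nuclear transport, rose by 1.56 ± 0.19 (SE, 10 arrays against 2), the transcription factors Sp3 by 1.57 ± 0.20 and Egr2 by 1.70 ± 0.26, Ccn1 by 1.75 ± 0.26, Rgcc, a cell cycle regulator, by 1.28 ± 0.19 and Slc6a6, the taurine transporter, by 1.29 ± 0.20, while Kcnn1 had a change of -1.30 ± 0.18. Their adjusted p-values ran from 0.015 to 0.048. Over days 14 to 56 alone none of the 7 passed, with adjusted p-values from 0.133 to 0.978: Ranbp1 had 0.073, Ccn1 0.067, Rgcc -0.033 and Kcnn1 -0.34, against 3.79, 4.29, 3.24 and -2.74 over days 1 and 7 alone, on the arrays with the high beta-actin difference. Sp3, Egr2 and Slc6a6 had 1.62, 1.45 and 1.07 over days 14 to 56, and in the whole set all 10 ligated arrays on the same side of sham. Slpi at 2.67, Palld, an actin-binding protein, at 1.69 and Spata1 at 1.11 had the next smallest p-values and did not pass, with adjusted p-values of 0.055, 0.055 and 0.063. Postn at 2.66, Timp1 at 1.59 and Col3a1 at 1.07 did not pass, with adjusted p-values of 0.249, 0.352 and 0.353.

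Matrix genes passed camera as higher for the mean of the 5 days, with 40 of 43 members above 0 and a median of 1.07. In limma 0 members passed over all genes and 23 when adjusted over the list alone. Among these were Col5a1 at 1.45, Tnc at 1.70, Tgfb2, a growth factor of scar formation, at 1.22 and Col1a1 at 1.90. The list had an adjusted p of 5.9e-19, and adjusted p = 0.636 with an estimated correlation. Hypertrophy and fetal genes passed camera as higher, with a median of 0.65 and adjusted p = 0.455 with an estimated correlation. Of their members 0 of 11 passed limma's test over all genes, with 7 at an unadjusted p under 0.05, and 7 passed when adjusted over the list alone, among them Nppb at 0.65 and Ccn2 at 1.38. Interferon response genes passed camera as lower, with a median of -0.58 and 17 of 19 members below 0, and adjusted p = 0.636 with an estimated correlation. In this list 0 members passed limma's test over all genes and 0 when adjusted over the list alone, with 7 at an unadjusted p under 0.05. On day 7 that list had a median of 0.76, with 17 of 19 members above 0. The other lists that passed were inflammation at 0.39, proliferation at 0.34 and insulin signalling at 0.32, higher, and ion channels at -0.18, fatty acid oxidation at -0.15 and oxidative phosphorylation at -0.14, lower. These 9 lists had adjusted p-values from 5.9e-19 to 0.023, and adjusted p = 0.455 to 0.808 with an estimated correlation. Of the other 25 lists none passed. Over days 14 to 56 alone, ion channels had a median of -0.033, inflammation genes 0.0033 and proliferation genes 0.23, with adjusted p-values of 0.779, 0.638 and 0.093.

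In total 20 probe sets passed for this mean, 18 higher and 2 lower, against 2031 at an unadjusted p under 0.05. The count rose to 2269 over days 1 and 7 alone and was 0 in limma over days 14 to 56 alone, where 1434 had an unadjusted p under 0.05; the 4 early arrays are those with the high beta-actin difference. It was 6 with quantile normalization and 7 with array medians set equal, 411 without the non-diabetic and 306 without the diabetic day 28 array, 9 and 7 without the diabetic and non-diabetic day 7 array, 10 without the diabetic day 1 array, 1 and 3 without the diabetic and non-diabetic day 14 array, 4 without the diabetic day 56 array, and 0 without the non-diabetic day 56 array or either sham array. None of the 7 named genes that passed did so in all of these.

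Over the days after ligation, 3430 probe sets had a negative and 1879 a positive slope per doubling of days over the 10 ligated arrays. That balance turned with array medians set equal, to 2917 higher and 2332 lower. Such a slope need not be a steady course. In limma 93 passed for day 7 minus day 1 and 0 over days 14 to 56 alone, where 5056 had an unadjusted p under 0.05. Ccn1 had a slope of -0.93 ± 0.05 (SE), Ccl20 of -0.86 ± 0.05, Reg3b of -0.84 ± 0.08, Ranbp1 of -0.84 ± 0.04 and Slpi of -0.80 ± 0.09. Ankrd2, the chemokines Ccl2 and Ccl7, Rgcc, Rps27l, Lcn2 and Orm1, an acute phase protein, had slopes from -0.80 to -0.64. Sohlh1 had a slope of 0.65, Rasgrf1, a Ras activator of neurons, of 0.54, Gabbr1, a GABA receptor subunit, of 0.50, Mfap4, a microfibril protein, of 0.47 and Kcnn1 of 0.46. LOC102549347, Fcrla, Rpap1, Ceacam9, Dus4l, Foxd3 and Ihh had slopes from 0.47 to 0.56. Timp1 had a slope of -0.63, Angptl4 of -0.46, Nppb of -0.13, Slc2a4 of 0.35, Col1a1 of 0.40, and the heavy chains of myosin Myh6 and Myh7 of 0.13 and 0.095. These 2 slopes depended on the probe set, as the other probe sets of Myh6 and Myh7 had 0.97 and 1.20, and the mean per gene symbol 0.55 and 0.65. A second probe set of Pdk4 passed in the direction opposite to its main one, which did not pass.

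For the slope 10 lists passed camera, with adjusted p-values from 5.7e-05 to 0.045, and adjusted p = 0.812 to 0.879 with an estimated correlation; of the other 24 lists none passed. Inflammation genes had 15 of 27 members lower with time over all genes, 16 when adjusted over the list alone and a median slope of -0.17, among them Cxcl1 at -0.53 and Il1b at -0.43. Macrophage markers had 11 of 19 lower, 12 when adjusted over the list alone, with Fcgr2b at -0.52, and neutrophil markers 4 of 5 lower by either adjustment, with S100a8 at -0.55. Ion channels had 5 of 15 higher by either adjustment, with Kcnip2, a subunit of the transient outward potassium channel, at 0.33. Smooth muscle markers had 4 of 10 higher, 6 when adjusted over the list alone, with Smtn at 0.23. Adult contractile genes, with Ldb3 at 0.17, calcium handling, with Ryr2, the calcium release channel, at 0.14, fibroblast markers, with Gsn at 0.24, and skeletal muscle markers, with Myh2 at 0.32, also passed as higher. Matrix genes passed as higher with a median of 0.012 and a mean of -0.0037, with 5 members higher, such as Col14a1 at 0.38, and 5 lower, such as Tgfb2 at -0.40. Over days 14 to 56 alone, the matrix list turned to a median of -0.53, with an adjusted p of 8.7e-04, smooth muscle markers to -0.10 and fibroblast markers to -0.36, with adjusted p-values of 0.932 and 0.081. Neutrophil markers at -0.35 and skeletal muscle markers at 0.020 did not pass there, with 0.327 and 0.187, while fatty acid oxidation genes had a median of 0.17, with an adjusted p of 4.8e-07.

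In total 5309 probe sets passed for the slope, 1879 higher and 3430 lower. The split was 2537 higher and 2464 lower with quantile normalization and 2917 higher and 2332 lower with array medians set equal. The count was 0 in limma over days 14 to 56 alone, where 5056 had an unadjusted p under 0.05, 93 for day 7 minus day 1, 3308 without the day 7 pair and 2077 without the day 56 pair. Without the day 1 pair Col1a1 turned to -0.75, with an adjusted p of 0.029, and Mfap4 to -0.45, with an adjusted p of 0.057. Without it Ccl20, Ankrd2, Lcn2, Orm1, Nppb, Slc2a4, Myh6 and Angptl4 no longer passed, with slopes of -0.21, -0.10, -0.27, -0.33, -0.078, 0.20, 0.044 and -0.13. The slopes of Sohlh1, LOC102549347, Rasgrf1, Gabbr1, Rpap1, Ceacam9, Dus4l, Foxd3, Ihh and Kcnn1 lay between 0.70 and 1.01 without it, that of Rps27l at -1.12 and that of Myh7 at 0.17. Without the day 56 pair Mfap4 had 0.72 and Col1a1 0.67. Myh6 and Myh7 also lost their calls without the day 7 or the day 56 pair, Myh6 without the day 14 pair and Timp1 without the day 56 pair. The arrays with a beta-actin difference of 0.98 to 1.00 lie at the early end of this slope.

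Whether the difference between diabetic and non-diabetic hearts changed with the operation or with time was tested by 2 interactions. The limma test called 0 probe sets for the diabetes difference after ligation minus that in sham, with 125 at an unadjusted p under 0.05, and 0 for its slope per doubling of days, with 838. The first rests on 1 sham pair and has 4 residual degrees of freedom, the second 3.

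At single time points the 2 arrays were compared without a test, as differences between pooled samples. Card9 was among the 5 genes with the largest lower difference at every time point, from -4.49 on day 14 to -2.53 on day 7. Pik3c2g had differences of 3.05, 3.14 and 3.55 on days 1, 7 and 28, and Angptl4 was higher in the diabetic array in sham and on days 14 and 56, where the non-diabetic array lay under the filter threshold of 5.20. On day 28 the diabetic minus non-diabetic difference was -3.44 for Ltbp2 and -3.40 for Col8a2, both matrix genes, and -3.99 for Gzmb, against 3.64 on day 14. Postn differed by 3.44 and Car3 by 4.17 on day 14. Probe sets at least 2-fold apart numbered 272 in sham, 589 on day 1, 189 on day 7, 1404 on day 14, 2213 on day 28 and 631 on day 56. Fam111a had differences of 4.85, -4.70, -4.67 and 6.28 on days 1, 7, 28 and 56, with no fixed direction. The lower array of the pair lay under that threshold for Card9 at every time point but day 1, for Pik3c2g on day 28, for Car3 on day 14 and for Fam111a on days 1, 28 and 56, so these sizes are against a level near background.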

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

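No test in this part was chosen after its result was seen. For each gene named for diabetes or always looked up, and for the median intensity, the beta-actin 3' to 5' difference and the spiked-in control Dap, the 6 arrays of a condition were searched for 1 array far from the others, by the gap to its nearest neighbour as a share of the whole range. Of 80 groups searched 6 had such an array, where chance gives 4. In the non-diabetic arrays, the gap for Acot1 was 0.819 of the range, with day 1 at 5.66 against a median of 4.40 on the other arrays, as log2 of the intensity plus 16. In the diabetic arrays, the gap for Bdh1 was 0.726, with day 1 at 6.94 against 5.91. Slc2a4 had a gap of 0.689 there, with day 1 at 6.71 against 8.87, and Myh6 one of 0.719, with day 1 at 10.8 against 12.1. The gap for Sctr in the diabetic arrays was 0.676, with day 14 at 6.88 against 5.02. Dap had a gap of 0.654 in the non-diabetic arrays, with day 14 at 11.4 against 9.55. No explanation was tested for these values.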

How the results depend on the processing

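The comparisons restricted to some of the days, and those without the day 14 and day 28 pairs, were chosen after seeing the data. Of 2254 comparisons of a reported value with its value under an alternative, 89 changed sign, 66 of them with neither value past the threshold and 2 with both past it, Col1a1 and the matrix list in the slope over days. The cause was not tested, except that fewer arrays, fewer probe sets or fewer days enter where the setting says so. Low signal over background limits dim probe sets, and 12 pooled arrays limit every comparison.

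For diabetes, the count of 70 became 14 without a time point term, 315 with array weights, 35 on sham and days 14 to 56 alone, 2 on days 1 and 7 alone and 38 without the day 14 and day 28 pairs, and ran from 6 to 92 as each pair was left out. For the mean of the 5 days minus sham, the count of 20 became 31 with an offset of 64, 6 with quantile normalization, 7 with array medians set equal, 89 without a filter, 13 without a variance trend, 5 with the mean per gene symbol, 2257 with array weights and 3470 in an F test over the 5 days. In limma it was 0 without time terms and 0 over days 14 to 56, where 1434 had an unadjusted p under 0.05, and 2269 over days 1 and 7, and ran from 0 to 411 as each array was left out. Without a filter day 1 had 2384 calls, day 7 2775 and day 56 10; with the upper 40% of probe sets day 1 had 638 and day 7 481; with the mean per gene symbol they had 623 and 511. As each sham array was left out, the counts ran from 187 to 316 for day 1 and from 168 to 286 for day 7, and were 0 in limma for each of days 14, 28 and 56. With an offset of 64 the split was 889 higher and 501 lower on day 1 and 1076 higher and 472 lower on day 7. With an offset of 1, day 56 had 2 calls and the interaction of diabetes with ligation 1; as each pair was left out the latter stayed at 0. For the slope over days, the count of 5309 became 3328 with the upper 40% of probe sets, 2933 with the mean per gene symbol, 0 in limma over days 14 to 56, where 5056 had an unadjusted p under 0.05, and 93 for day 7 minus day 1, and ran from 2077 to 6471 as each pair was left out. Of the lists, 6 passed camera for diabetes, 9 for the mean of the 5 days and 10 for the slope. These became 0, 0 and 0 with an estimated correlation. For the slope 5 passed without a filter, and for diabetes 10 passed without the day 14 and day 28 pairs, and from 5 to 10 as each pair was left out. Further lists past camera for diabetes as 1 pair was left out were erythroid markers at -0.32, mesothelial markers at -0.24 and immediate early genes at 0.31 without the day 7 pair. Without the day 28 pair they were glycolysis at -0.058, oxidative phosphorylation at -0.095, contractile genes at -0.098 and inflammation genes at 0.25, and without the day 56 pair smooth muscle markers at -0.32 and immediate early genes at 0.26, besides the matrix list. Erythroid markers also passed with the mean per gene symbol, at -0.31, and on sham and days 14 to 56 alone, at -0.51, as did the matrix list there, at -0.21. Without the day 14 and day 28 pairs the further lists were ketone body metabolism at -0.36, oxidative phosphorylation at -0.088, contractile genes at -0.085, inflammation genes at 0.18 and the interferon response at 0.35, the last with an adjusted p of 0.0052. Over days 14 to 56 alone, further lists past camera for the slope were complement at -0.65, lymphocyte at -0.50, proliferation at -0.45, interferon at -0.36 and glycolysis at 0.042. Oxidative phosphorylation passed for that slope as higher with a median of -0.019, where the median of all kept probe sets was -0.046. Against sham, skeletal muscle markers at 0.19 and circadian genes at 0.13 passed over these days.

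All 24 genes named for diabetes passed under both scalings, without a filter and with array weights, 14 on sham and days 14 to 56 alone and 1 on days 1 and 7 alone. The weights were equal within a pair, at 3.42 for the sham arrays and 0.415 for the day 28 arrays. They follow how well a pair's diabetes difference matched that of the other pairs, so passing with them adds little. Of 24 genes named for the slope 19 passed whichever pair was left out, 0 over days 14 to 56 and 5 for day 7 minus day 1.

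The following values changed sign. For diabetes, Atp2a2 went from -0.0095 to 0.0099 with the mean per gene symbol and to 0.037 on sham and days 14 to 56 alone, and Acta1 from -0.030 to 0.076 with array weights. On days 1 and 7 alone, Nppb went to 0.086, Timp1 to 0.29, Acta1 to 0.12 and Col3a1 to 0.23, and without the day 14 and day 28 pairs, Timp1 went to 0.33, Acta1 to 0.028 and Col3a1 to 0.071. As each pair was left out, Acta1 ran from -0.079 to 0.033, Atp2a2 from -0.073 to 0.036, Col1a1 from -0.52 to 0.15, Col3a1 from -0.37 to 0.18, Spp1 from -0.12 to 1.24 and Timp1 from -0.49 to 0.36. On day 7, Myh6 went from 0.10 to -0.14 with array medians set equal and to -1.77 with the mean per gene symbol, where other probe sets of the gene enter the mean. In the mean of the 5 days, Rgcc went from 1.28 to -0.033 over days 14 to 56. In the slope over days 14 to 56, Fcrla went to -0.30, Mfap4 to -0.55, Kcnn1 to -0.16, Ccn1 to 0.082, Slc2a4 to -0.12 and Col1a1 to -0.72. In day 7 minus day 1, Rasgrf1 was at -0.027, Fcrla at -0.055, Rpap1 at -0.014, Ceacam9 at -0.077, Ihh at -0.42 and Kcnn1 at -0.28. As each pair was left out, the slope of Col1a1 ran from -0.75 to 0.67 and that of Mfap4 from -0.45 to 0.72.

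Of the list medians, with the mean per gene symbol the interferon list went from -0.0050 to 0.015 for diabetes and the circadian list from -0.045 to 0.015 for the slope. For diabetes on sham and days 14 to 56 alone, ion channels went to 0.050, neutrophil markers to -0.14, circadian genes to 0.068, glucocorticoid-responsive genes to 0.097 and apoptosis genes to 0.0083. Without the day 14 and day 28 pairs, hypertrophy genes went to 0.028, calcium handling to -0.019, matrix genes to 0.071, interferon genes to 0.35, which passed, macrophage markers to 0.067, fibroblast markers to 0.026 and Schwann cell markers to 0.0099. For the slope over days 14 to 56, fatty acid oxidation went from -0.015 to 0.17, insulin signalling from -0.012 to 0.14, matrix genes from 0.012 to -0.53, smooth muscle markers from 0.12 to -0.10, fibroblast markers to -0.36 and circadian genes from -0.045 to 0.010; of these the fatty acid oxidation, insulin, circadian and matrix lists passed there, with adjusted p-values of 4.8e-07, 0.014, 0.014 and 8.7e-04. As each pair was left out, the diabetes medians ran from -0.032 to 0.091 for antioxidant genes, -0.080 to 0.0011 for apoptosis, -0.0074 to 0.14 for calcium handling, -0.15 to 0.065 for circadian genes, -0.098 to 0.0068 for contractile genes, -0.30 to 0.16 for matrix, -0.27 to 0.16 for fibroblast markers and -0.12 to 0.067 for glucocorticoid-responsive genes. They ran from -0.074 to 0.032 for glycolysis, -0.22 to 0.044 for heat shock genes, -0.074 to 0.054 for hypertrophy genes, -0.16 to 0.21 for interferon genes, -0.016 to 0.085 for lipogenesis, -0.35 to 0.14 for macrophage markers, -0.14 to 0.30 for neutrophil markers, -0.13 to 0.068 for ion channels, -0.16 to 0.073 for Schwann cell markers and -0.047 to 0.020 for skeletal muscle markers.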

Other observations

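The tests of day 7 against day 1, of lists on day 56, of the day 28 pair and of the order of days were chosen after seeing the data; the test of other probe sets of a gene, that of contractile genes and the counts of other splits were not.

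In day 7 minus day 1, 13 of 34 lists passed camera, and 0 did with an estimated correlation. Interferon response genes had a median of 1.63 with 18 of 19 members above 0 and 17 past when adjusted over the list alone. Their mean went from -1.21 to 1.36 in the diabetic arrays and from -0.76 to 0.16 in the non-diabetic ones, so the pooled value comes mostly from the diabetic pair. Fibroblast markers had a median of 1.16 with all 15 members above 0. Complement and antigen presentation genes had a median of 0.77 with 21 of 22 members above 0. Neutrophil markers had a median of -1.38 with 0 of 5 above 0, inflammation genes of -0.71 and heat shock genes of -0.42. Over all genes limma called 3 members of the interferon, 3 of the fibroblast and 4 of the inflammation list, and 0 of the complement, neutrophil and heat shock lists, with 11, 3 and 4 at an unadjusted p under 0.05. These 6 lists had adjusted p-values from 1.8e-19 to 3.9e-06 in camera, and adjusted p = 0.256 to 0.272 with an estimated correlation.

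On day 56, complement and antigen presentation genes had a median of -0.77 against sham with 20 of 22 members below 0, lymphocyte markers of -0.61 and inflammation genes of -0.58, with adjusted p-values of 3.9e-05, 0.0023 and 0.0093. They had adjusted p = 0.548, 0.426 and 0.607 with an estimated correlation. Inflammation genes had gone the other way on day 28, with a median of 0.39 and an adjusted p of 2.2e-05, and adjusted p = 0.535 with an estimated correlation. Circadian clock genes had a median of 0.089 and a mean of 0.42 on day 56, with an adjusted p of 3.8e-04, and adjusted p = 0.326 with an estimated correlation. The differences between diabetic and non-diabetic arrays correlated across genes by -0.068 to 0.386 between pairs of time points, with 13 of 15 pairs above 0; genes are not independent replicates.

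The calls at day 1 and day 7 lie on the 4 arrays with a high 3' to 5' difference of beta-actin, so the 2 days could differ from sham through loss of 5' RNA. The GAPDH difference did not set these arrays apart. For matrix genes a loss of 5' RNA is argued against, as day 7 and day 1 share the high beta-actin difference while the matrix list lay 1.58 higher on day 7, with 39 of 43 members above 0. For all called genes that loss stays open: 74.9% of the other probe sets of called genes moved the same way, between the 65% and 80% that would have decided. A response to the infarct on these days is the biological explanation the design gives, and it cannot be told apart from RNA quality for those genes. Nor can it be told apart from separate processing of these 4 arrays, as no batch or scan date was available. After a shared prefix their titles hold a number alone, where those of the other arrays hold letters.

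The 2 arrays of day 28 lay further apart than any other pair, with 2213 probe sets at least 2-fold apart. A swap of the condition labels between these 2 arrays is argued against, since 84.8% of the 92 probe sets called for diabetes without that pair had the same sign in it. A smaller share of muscle that raises all other tissue alike in the non-diabetic pool stays open. The matrix and endothelial medians of -1.75 and -0.26 lay -1.49 apart. That gap was outside the 95% prediction interval of -0.85 to 1.72 from the 5 other pairs of arrays, where it ran from -0.15 to 0.97. The pair was picked because its arrays lay far apart, so this interval cannot decide. As means over members, muscle lists lay higher in the diabetic day 28 array. The differences were 0.25 for contractile genes, 0.28 for calcium handling and 0.51 for ion channels, each the highest of all time points. More non-muscle tissue of some kinds in that pool stays open: the medians of matrix, fibroblast, macrophage and smooth muscle lists lay at -1.75, -0.98, -1.40 and -0.63, and the highest of the 5, endothelial markers at -0.26, was within its spread over resampled genes, 0.18, of the -0.3 set as the bound. A different course of scarring in diabetic rats may also give this and was not tested. Nor was a mix-up of days among days 14 to 56 tested. Across genes, the diabetic day 28 array correlated best with the diabetic day 56 array, at 0.9765 against 0.8983 with its partner. The non-diabetic day 28 array correlated best with the diabetic day 14 array, at 0.9743. The non-diabetic day 56 array carries an age of 22 weeks, that of the day 28 arrays.

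The difference between diabetic and non-diabetic arrays in genes of fatty acid oxidation was higher on each later day after ligation, with a mean of -0.070, 0.42, 0.70, 0.94 and 1.07 on days 1, 7, 14, 28 and 56, against 0.70 in sham. No other order of the 5 days gives as strong a relation, with an exact two-sided permutation p of 0.00833, the smallest that 120 orders can give. Adjusted over 34 lists this is 0.283, which is what the smallest p gives for a single list, so the test could not pass and the hypothesis that the difference grows after ligation stays open. Whether a changing share of muscle in the pools contributes stays open. The contractile list's difference was 0.41 higher on day 56 than on day 1 where that of fatty acid oxidation was 1.14 higher, which neither bound set for it decides. The contractile difference was 0.25 on day 28 and 0.043 on day 56. Among lists of other cells, fibroblast markers rose by 1.08 from day 1 to day 56, smooth muscle by 1.06 and adipocyte markers by 0.83. Neutrophil, lymphocyte and erythroid markers changed by -0.80, -0.38 and -0.87. Labelled age also differed within the day 56 pair, at 26 weeks in the diabetic and 22 in the non-diabetic array.

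The 70 probe sets called for diabetes were set against other splits of the arrays. Of 96 splits into 6 and 6 drawn, 1 gave as many, the real one, and the highest other gave 13. Of 32 swaps of the conditions within time points, 1 gave as many, again the real one, and the highest other gave 0. With 32 swaps the real one can be at best 1 of 32, so chance is argued against but not excluded. The drawn splits could put both arrays of a time point on the same side, which leaves fewer pairs to compare, so they add less.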
